A study of Mus musculus with 4 samples.

How the data were processed

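Messenger RNA was measured in 4 samples of mouse embryonic stem cells on 1-colour Agilent arrays, with 1 array per sample. The labels name 2 controls, cultured with tetracycline (Tc, 1000 ng/mL), and 2 samples with knock-down of FBL, cultured without Tc, all for 2 days with leukaemia inhibitory factor (LIF). The labels do not say whether the samples of a group come from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. The sample titles gave the groups, and every deposited column could be mapped to a sample.

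Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.3.1, and each deposited spot intensity is a background-subtracted and spatially detrended signal that is not scaled between arrays. The deposited value table holds log2 values: on each array, 99.7% to 99.8% of its entries lay within 0.01 of the log2 processed signal minus 1 constant. Its column medians were −3.85 and −3.98 for the controls and −3.94 and −3.91 for the knock-down samples, and its 75th percentiles lay at 0 to within 0.01. Its scale is therefore log2 after shifting each array to its 75th percentile, with no centring of probes, and its direction is that of the signal. Of its 41267 entries per array, 41174 matched a probe of the scanner files. The software that made the table is not given in the sources used here.

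Each array held 45018 spots, of which 43379 were not controls, for 41174 probes. Between 96 and 138 spots per array carried an outlier flag and were left out, and 50 probes with every spot flagged on any array were dropped. No spot was saturated. Spots of a probe were averaged on the log2 scale. The share of spots well above background was 61.4% and 63.4% in the controls and 64.5% and 59.9% in the knock-down samples, and the number of arrays limits the precision.

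The processed signal was taken to log2 and each array's 75th percentile over non-control probes was subtracted. A probe entered the test when it was well above background on both arrays of at least 1 group, which 25077 probes were. The files carry no gene name column, although the design had assumed one, so names came from the accession of each probe, matched without version to the RefSeq gene table of assembly GRCm38.p6. That table named 24375 probes with 1 gene each (17016 genes) and left 16799 without a name, which kept their accession. No coordinates are given because the array design refers to another build. A gene was represented by its probe with the highest mean level over the 4 arrays, which left 19338 genes, 12814 of them with a symbol.

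Groups were compared with limma 3.58.1 (lmFit and eBayes with the default prior, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Log2 changes are knock-down minus control, with the standard error of the fit. A gene rose or fell where it passed that threshold, and n is 2 per group throughout. For a probe well above background on both arrays of one group and on neither of the other, the change is given as at least N-fold: the mean of the brighter group against, per array of the dimmer group, the higher of the probe's own signal and the lowest signal among probes well above background.

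The main test, the alternatives, the rule for naming genes and 28 gene lists were chosen before the data were examined. The lists cover p53 target genes, small nucleolar ribonucleoprotein components, ribosome biogenesis factors, the RNA polymerase I machinery, cytosolic and mitochondrial ribosomal proteins, small nucleolar RNA host genes, pluripotency genes, primed epiblast genes, markers of endoderm, primitive streak and mesoderm, neural ectoderm, trophectoderm and fibroblasts, 2-cell-like state genes, DNA replication, mitosis, CDK inhibitors, apoptosis, the integrated stress response, the unfolded protein response, heat shock, oxidative phosphorylation, glycolysis and hypoxia, sterol synthesis, interferon response, LIF and STAT3 targets, and the MYC family. The 27 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over these lists. Camera p-values at the preset correlation compare the members of a list with all other genes. They rest mainly on the spread across genes and do not measure replication between samples. Beside this test stand camera with an estimated correlation, fry, and the percentile of the list's median among 10000 random lists matched on mean level in 20 bins. Members were also counted with p adjusted over the list alone.

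Named genes are Fbl, 7 genes fixed by name, the 10 rising and 10 falling genes with the largest change among called genes with a plain symbol, separate groups and signal well above background on all arrays, up to 2 rising and 2 falling called members of each list (or up to 2 of its brightest members where none passed), and up to 3 genes per direction that were well above background in one group alone. Further members of the p53 and stress response lists, and the Notch, Wnt and transfer RNA synthetase genes, were named after their values were seen.

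The alternatives were median scaling, quantile normalization, the 75th percentile over probes well above background on all arrays, normexp background correction with an offset of 50, no filter on dim probes, only probes well above background on all arrays, the mean over a gene's probes, eBayes with trend and with trend and robust, the authors' value table, the slide as a block, the replicate number as a block, and leaving out each array. The files hold no mean spot signal, so normexp used the median spot signal and the median local background. Its offset of 50 is near the median processed signal of the arrays, 34.3 to 52.2, so it shrinks the changes of dim genes. An unfiltered fit with trend was added after the data were seen. Controls 1 and 2 and knock-down 1 shared slide 1 and scan 1, and knock-down 2 was alone on slide 2 and scan 2. A fit with the slide as a block is therefore the same as the comparison within slide 1, which leaves out knock-down 2.

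The method was tested on simulated data with 50 genes changed at each of 4 sizes over the 19338 genes. It recovered 0% of genes changed by 0.5 on the log2 scale, 16% of those changed by 1, and 100% of those changed by 2 and by 3, with 9 false calls among 117. A simulated shift of 1 list was called with the preset correlation and not with an estimated one. Of the unmoved lists among the 27, 0 were called. The simulated genes varied independently, whereas the estimated correlation in the data was 0.58 for the stress response list and 0.80 for cytosolic ribosomal proteins. The simulation therefore does not show how often the preset correlation gives false calls for lists with correlated members. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.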

Results

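Gene expression was measured in 4 samples of mouse embryonic stem cells in which the expression of FBL depends on Tc. FBL, fibrillarin, is the nucleolar enzyme that methylates ribosomal RNA at the 2'-hydroxyl, guided by box C/D small nucleolar RNAs. The 2 control samples were kept with Tc and the 2 knock-down samples without it. Between 24495 and 26403 of the 41174 probes were well above background per array, and the 75th percentile of the processed signal was 561 and 798 in controls 1 and 2 and 642 and 505 in knock-down samples 1 and 2. The comparison asks which transcripts differ after 2 days of FBL knock-down while the cells stay in LIF.

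Fbl itself fell 5.34-fold (log2 change −2.42 ± 0.25 SE, n = 2 per group, limma adjusted p = 5.01e-04). Its level relative to the 75th percentile of the array was 8.63 and 8.12 in the controls and 5.98 and 5.94 in the knock-down samples, read by 1 probe. Target genes of the tumour suppressor p53 rose as a group in camera with a preset correlation, where 19 of 37 measured members rose and 0 fell, and the group call was lost with adjusted p = 0.484 with an estimated correlation. Genes of the integrated stress response, which is driven by the transcription factor ATF4, fell as a group in the same test, where 17 of 32 members fell and 1 rose, and that call was lost with adjusted p = 0.820 with an estimated correlation. With 2 residual degrees of freedom, camera with an estimated correlation passed 0 of 27 lists, so these losses do not tell whether correlated members explain the shifts. The correlation estimated from the 4 samples was 0.034 for the p53 list and 0.58 for the stress response list. The preset of 0.01 therefore lay further off for the stress response list. Before adjustment, camera with an estimated correlation gave p = 0.0179 for the p53 list and 0.179 for the stress response list. Pou5f1, which encodes the pluripotency factor OCT4, had a log2 change of −0.07 ± 0.25 (adjusted p = 0.925).

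Across all 19338 genes tested with limma, 739 rose and 499 fell, or 6.40% of them. Of the former 669 and of the latter 410 changed at least 2-fold. A symbol was held by 543 of the rising and 301 of the falling genes. The others are accessions counted as genes of their own, so some may belong to a named gene. The smallest called change was 0.87 on the log2 scale, and the median change of all genes was −0.06. Both knock-down values lay on one side of both control values for all 1238 called genes, which the test all but requires. They did so for 51.1% of all genes, where chance gives 33.3% for a single gene. Genes share differences between arrays, so the share over all genes can leave 33.3% without an effect of the knock-down. Within slide 1, which equals the fit with the slide as a block and leaves out knock-down 2, 380 genes rose and 195 fell, and Fbl had an adjusted p of 1.70e-05. Without control 1 the counts were 2379 and 1801, without control 2 they were 1123 and 1359, and without knock-down 1 they were 457 and 328. Of 63 called genes named by rule, 41 passed within slide 1, 43 without knock-down 1 and 55 under normexp background correction, which moved 27 of the 63 changes by more than 1.5 times. Within slide 1, without knock-down 1 and under normexp, the estimated prior carried infinite degrees of freedom. Each of these fits gave every gene the same variance, so passing depended on the size of the change alone. Within slide 1, 2 of the 63 changes moved by more than 1.5 times, and without knock-down 1, 0 did. The loss of a call in either fit, here or below, therefore does not by itself show a different change. With no filter on dim probes 0 genes passed, Fbl included (limma adjusted p = 0.108), and 2967 had an unadjusted p under 0.05. The 2 controls differed from each other more than the 2 knock-down samples did, with a standard deviation of the difference across genes of 0.51 against 0.32. Fits without control 1 or control 2 take the spread from the knock-down pair alone. A call gained in these fits, here or below, therefore does not by itself show a firmer change.

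**Figure D1:**
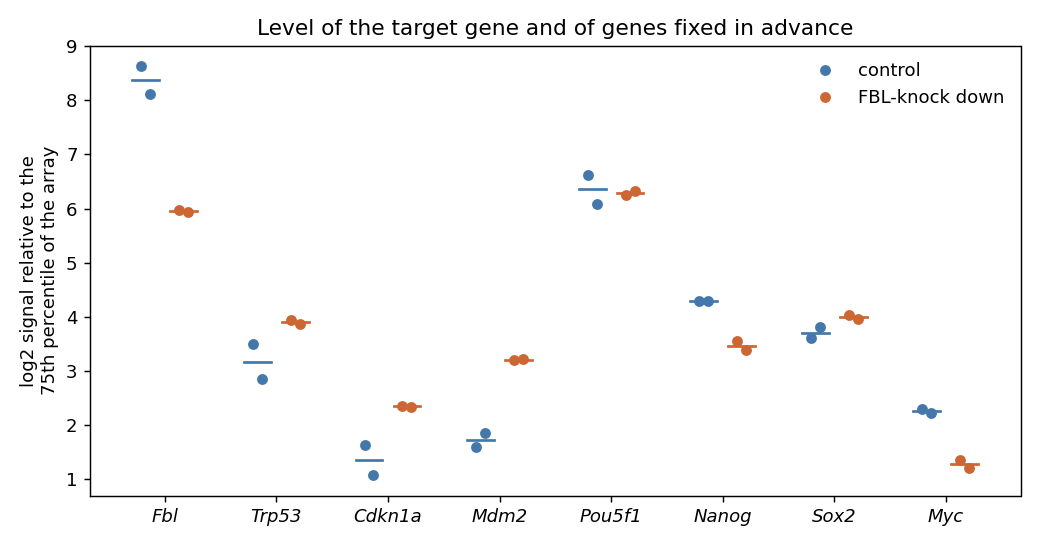
Level of Fbl and of 7 genes fixed by name, as log2 signal relative to the 75th percentile of the array, in the 2 controls and the 2 knock-down samples; each point is 1 array and each line the mean of its group. Fbl lay at 8.63 and 8.12 in the controls and at 5.98 and 5.94 in the knock-down samples.

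Among the largest rises of genes with a plain symbol and signal well above background on all arrays were those of Cpz, a secreted carboxypeptidase with a Wnt-binding domain, at 16.4-fold (log2 4.03 ± 0.31), Ms4a10 at 13.3-fold, Tff3, a secreted trefoil peptide, at 12.0-fold, and Gfra3, a receptor for the ligand artemin, at 11.9-fold. Cd109, Gadd45g, Ltb4r2 (a leukotriene B4 receptor), Alox5 (5-lipoxygenase, the first enzyme of leukotriene synthesis), Unc45b and Cdkl1 rose by 2.93 to 3.32 on the log2 scale. Under normexp the change of Cpz was 2.65, of Tff3 2.03, of Ltb4r2 2.04 and of Cdkl1 1.38. Among the largest falls of genes with a plain symbol and signal well above background on all arrays were those of Nupr1, a stress-induced chromatin protein, at 19.7-fold (log2 −4.30 ± 0.23), Serpinf1, which encodes the anti-angiogenic factor PEDF, at 12.3-fold, and Chac1, which degrades glutathione, at 10.6-fold. Vegfa, the endothelial growth factor, fell 5.17-fold. Jdp2, Inhbe, Adgrd1, Pck2 (the mitochondrial phosphoenolpyruvate carboxykinase) and Parvg fell by log2 −2.34 to −2.16. Under normexp the change of Serpinf1 was −2.26, of Inhbe −1.17 and of Adgrd1 −0.74, and the call of Parvg ended (−0.15, adjusted p = 0.853). Zic2 fell with log2 −2.21 ± 0.53 (adjusted p = 0.0374), and its controls lay apart at −3.68 and −1.53. Its change was −1.14 without control 2 and −0.82 under normexp. Its call ended with quantile normalization (adjusted p = 0.123), with the 75th percentile over bright probes, those well above background on all arrays (0.0860), and with trend and robust (0.358). Matn1 rose at least 7.40-fold, Kcne1l at least 5.04-fold and Tmem269 at least 4.80-fold from controls not well above background. The knock-down values of Tmem269 lay apart at −5.54 and −1.48, so its bound rests mainly on knock-down 2. The call of Tmem269 ended with quantile normalization (adjusted p = 0.0776), with trend and robust (0.375), without control 1 (0.107) and without control 2 (0.152), and its change fell from 4.56 to 2.52 without knock-down 2. Magea4 fell at least 8.72-fold, Kcnj16 at least 6.49-fold and Crhbp at least 4.62-fold to knock-down values not well above background. Under normexp these 6 changes were smaller than their bounds, at 0.999, 0.92 and 0.74 for the rises and −0.89, −1.11 and −0.87 for the falls.

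Of the p53 targets, Plk2, a polo-like kinase, rose 5.48-fold (log2 2.45 ± 0.22, adjusted p = 2.95e-04) and Ephx1, the microsomal epoxide hydrolase, 5.11-fold. Mdm2, the ubiquitin ligase that degrades p53, rose 2.80-fold (log2 1.49 ± 0.23, adjusted p = 0.00406), with a change of 1.5 at its other probe. Cdkn1a, the cell cycle inhibitor p21, rose 2.00-fold (adjusted p = 0.0467), a call that ended within slide 1 (adjusted p = 0.425) and without knock-down 1 (0.35). The death genes Pmaip1, Fas, Perp, Apaf1 (with 1 of its 2 other probes the opposite way) and Pidd1 rose by 1.35 to 2.03 on the log2 scale, and the antiproliferative genes Btg2 (2.07) and Trp53inp1 (1.78) rose too. Eda2r rose at least 1.76-fold from controls not well above background; under normexp its change was 0.066 and that of Fas 0.88. Bax (0.66, adjusted p = 0.176), Bbc3 (0.65, adjusted p = 0.174), Tnfrsf10b (0.57, adjusted p = 0.204) and Gadd45a (−0.02) did not pass. Trp53, the gene of p53 itself, had a log2 change of 0.74 ± 0.27 (adjusted p = 0.150) and 0.15 at its other probe, and passed with trend (adjusted p = 0.0439), with trend and robust (0.0131), unfiltered with trend (0.0111) and without control 1 (0.0189). Over the list, 29 members rose with p adjusted over the list alone. The median was 0.90, or 0.86 with Eda2r at its bound, and camera gave an adjusted p of 1.35e-19. The call was lost with adjusted p = 0.484 with an estimated correlation, and fry gave an adjusted p of 0.0279. Within slide 1 the median was 0.95 (camera adjusted p = 7.42e-21) and 12 members rose, with Apaf1 (adjusted p = 0.101) and Pidd1 (0.0509) no longer among them. Without knock-down 1, 12 rose too, Apaf1 (adjusted p = 0.0563) not among them, and without control 1, 30 rose.

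Of the stress response genes, Nupr1 (−4.30) and Chac1 (−3.40) fell, and so did Vldlr (−3.79), a lipoprotein receptor that was well above background on 1 of the 2 knock-down arrays. Fgf21 fell at least 1.47-fold to values not well above background; under normexp its change was −0.088 and that of Vldlr −1.16. Atf4 itself fell (log2 −1.56, adjusted p = 0.00356), as did the serine and one-carbon genes Psat1 (−1.76), Phgdh (−1.04), Psph (−1.01) and Mthfd2 (−1.93), asparagine synthetase Asns (−1.16) and the aminoacyl-tRNA synthetases Nars (−1.57), Aars (−1.14) and Gars (−1.02). Ddit4, an inhibitor of mTORC1 and also a p53 target, rose (1.66 ± 0.25). Ddit3 (0.45, adjusted p = 0.311), Trib3 (−0.80, adjusted p = 0.0840) and Atf5 (−0.93, adjusted p = 0.0537) did not pass. With p adjusted over the list alone, 22 fell and 1 rose. The median was −1.01, or −0.96 with Fgf21 at its bound, and camera gave an adjusted p of 1.29e-13. The call was lost with adjusted p = 0.820 with an estimated correlation, and fry gave an adjusted p of 0.0821. Within slide 1 the median was −0.96 (camera adjusted p = 2.02e-19) and 8 members fell, and Asns, Phgdh, Psph, Aars and Gars did not pass there (adjusted p = 0.203 to 0.463) or without knock-down 1 (0.173 to 0.321), where 8 members fell as well.

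**Figure D2:**
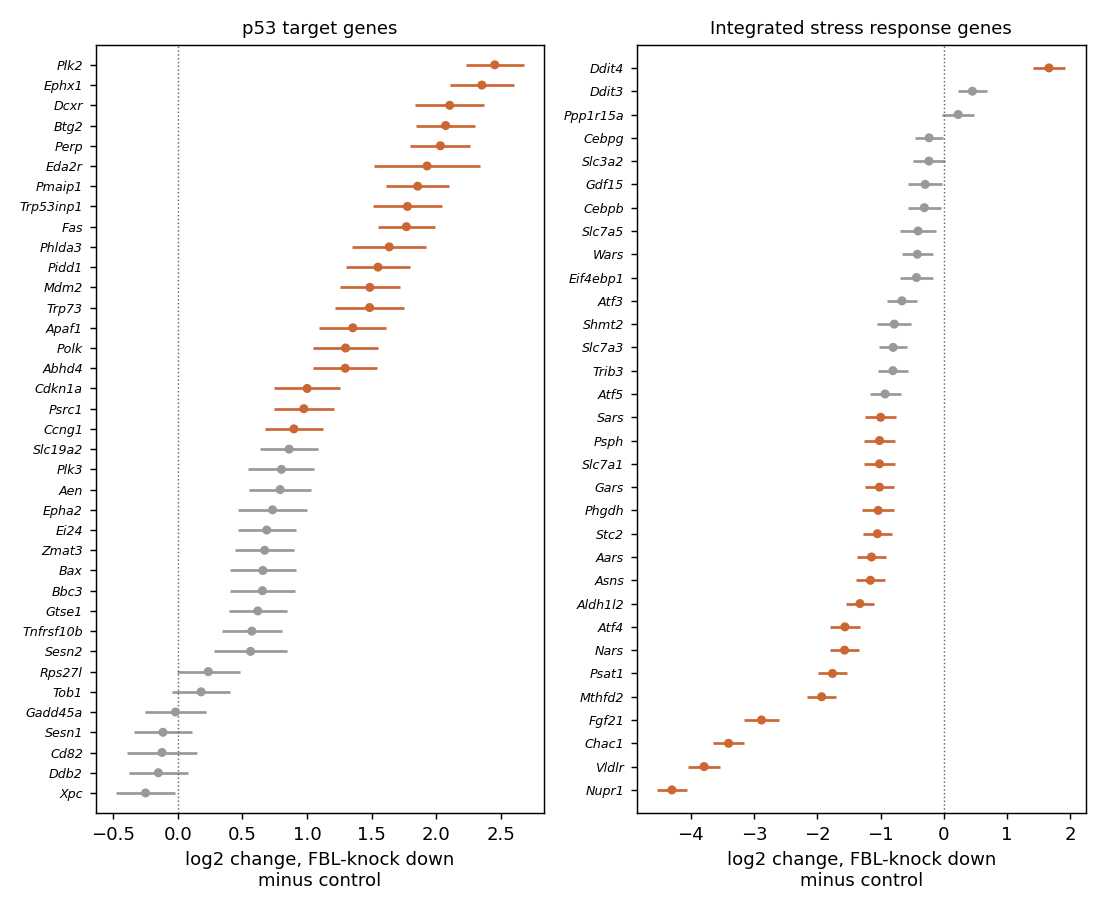
Log2 change, knock-down minus control, of each tested member of the p53 target list and of the integrated stress response list; points are estimates, lines are 1 standard error on each side, and coloured members passed the adjusted threshold over all genes. Plk2 is highest among the p53 targets at 2.45 and Nupr1 lowest among the stress response genes at −4.30.

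Other stress lists held fewer calls. Among endoplasmic reticulum chaperones and unfolded protein response genes 2 of 21 fell, also with p adjusted over the list alone, namely Herpud1 (−1.65) and Dnajc3 (−1.08, with 1 of its 3 other probes the opposite way), and the median was −0.12 (camera adjusted p = 0.240). That list passed under normexp (median −0.17, adjusted p = 0.0210), and with the mean over its probes the call of Dnajc3 ended (−0.46, adjusted p = 0.292). Hspa1a, the inducible HSP70, rose (1.27) among 15 cytosolic heat shock genes, as it did with p adjusted over the list alone, and their median was −0.20 (camera adjusted p = 0.461). In the interferon response list 2 of 13 fell and 5 did with p adjusted over the list alone, with a median of −0.42 and a camera adjusted p of 0.0393. That call was lost with adjusted p = 0.820 with an estimated correlation and with adjusted p = 0.0812 within slide 1, 0.115 without knock-down 1 and 0.365 without control 1, and the median was −0.09 under normexp. Oasl1 fell (−1.10), and Rsad2 (viperin) fell at least 1.53-fold to values not well above background, and both calls ended under normexp (−0.28 and −0.23). Within slide 1 the calls of Hspa1a (adjusted p = 0.122), Dnajc3 (0.425), Oasl1 (0.435) and Rsad2 (0.0912) ended. Without knock-down 1 they ended too (0.111, 0.187, 0.152 and 0.444 in that order), and that of Rsad2 also without control 2 (0.0583), with quantile normalization (0.0788), with trend (0.153) and with trend and robust (0.121).

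None of 17 small nucleolar ribonucleoprotein components passed in limma, over all genes or with p adjusted over the list alone, and Nhp2 (0.11) and Ruvbl1 (−0.65, adjusted p = 0.163) were the brightest of them, Ruvbl1 passing without control 2 (adjusted p = 0.0353), with a list median of −0.23 (camera adjusted p = 0.354, and 0.0443 under normexp). None of 76 ribosome biogenesis factors passed either, adjusted over the list alone included, and 60 were lower, with a median of −0.21, a camera adjusted p of 0.0512 and a fry adjusted p of 0.00852. The median lay at the 0.03 percentile of random lists matched on level. The list passed camera in 7 of 17 alternatives, namely under normexp (adjusted p = 3.53e-04), with no filter (0.0470), over bright probes (0.0434), with trend and with trend and robust (0.0371 each), without control 1 (0.0239) and unfiltered with trend (0.0189). Its highest adjusted p was 0.311, without knock-down 1. Of these Npm1 had a change of −0.10 and Ppan 0.03. Ttf1, the RNA polymerase I termination factor, rose (1.47 ± 0.25) as the only 1 of 15 genes of that machinery to pass, also with p adjusted over the list alone, while the list's median was −0.03 and its mean 0.05 (camera adjusted p = 0.743). None of 79 cytosolic ribosomal protein genes passed, adjusted over the list alone included. Their median was −0.01 and their mean −0.03, camera pointed upwards (adjusted p = 0.956), Rps18 had a change of 0.07 and Rpl7a 0.11, and the list differed by −0.43 between control 2 and control 1. It passed upwards without control 1 (median 0.21, adjusted p = 0.0294) and downwards without control 2 (−0.20, 0.00667). Mrpl19 fell (−0.93) among 72 mitochondrial ribosomal protein genes, 0 with p adjusted over the list alone (median −0.13, camera adjusted p = 0.175), and its call ended within slide 1 (adjusted p = 0.656), without knock-down 1 (0.351) and with quantile normalization (0.0523). That list passed without control 2 (median −0.28, adjusted p = 0.00282) and under normexp (0.00479) and had a median of −0.03 without control 1. Of 16 small nucleolar RNA host genes 1 was measured, Snhg3 (0.01), so that list was not tested.

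Genes of cell identity went both ways. Of 32 pluripotency genes 2 rose and 4 fell, against 3 and 7 with p adjusted over the list alone (median −0.18, camera adjusted p = 0.175). The list passed downwards under normexp (median −0.25, adjusted p = 0.00159). Lefty1, an inhibitor of Nodal signalling, rose (1.36), and Fut4 rose at least 1.49-fold from controls not well above background. Nr0b1 (−1.17) and Tfcp2l1 (−0.96), transcription factors of the naive state, fell. Within slide 1 none of the 6 called genes of this list passed in limma (Lefty1 0.0651, Fut4 0.0996, Nr0b1 0.277 and Tfcp2l1 0.581 as adjusted p), and without knock-down 1 these 4 did not pass either (0.0833, 0.0943, 0.137 and 0.336). Under normexp the change of Fut4 was 0.15. With quantile normalization the calls of Fut4 (adjusted p = 0.0705) and Tfcp2l1 (0.0903) ended, as did that of Fut4 with trend (0.0979) and with trend and robust (0.0627) and that of Tfcp2l1 with the 75th percentile over bright probes (0.0616). Nanog had a log2 change of −0.83 ± 0.23 (adjusted p = 0.0609) and Sox2 one of 0.29 (adjusted p = 0.554). That of Nanog passed in 8 alternatives, which include both fits without a control array. Those fits take the spread from the knock-down pair alone. Of 11 primed epiblast genes 5 rose and 2 fell, against 6 and 3 with p adjusted over the list alone. Otx2 (1.69) and Sall2 (1.65) rose, while Zic2 and Foxd3 (−0.92) fell. The call of Foxd3 ended within slide 1 (adjusted p = 0.711), without knock-down 1 (0.367) and with quantile normalization (0.0528), and that of Zic2 with quantile normalization (0.123), the percentile over bright probes (0.0860) and trend and robust (0.358). The list's median was 0.74 and its mean 0.29, with a camera adjusted p of 0.0950 and a fry adjusted p of 0.0187. The median was 0.32 under normexp, where camera passed (adjusted p = 0.0384), 0.20 over bright probes and 0.05 with no filter. All 5 tested 2-cell-like state genes were higher, 0 passing over all genes and 4 with p adjusted over the list alone, among them Tcstv1 (0.85, adjusted p = 0.0515) and Tcstv3 (0.78, adjusted p = 0.0733), both of which passed without control 1 (0.0271 and 0.0320) and without control 2 (0.0271 and 0.0345). Their median was 0.83 and camera gave an adjusted p of 0.00366, lost with adjusted p = 0.722 with an estimated correlation. The median was 0.39 under normexp and 0.24 with no filter, where the call ended too (adjusted p = 0.0985).

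Lineage markers also split. In the primitive and visceral endoderm list Cubn rose (1.28) and Sox7 (−2.16) and Lama1 (−1.01) fell among 20, against 1 up and 3 down with p adjusted over the list alone (median −0.07, camera adjusted p = 0.722). In the primitive streak and mesoderm list Wnt3 (2.21) and the VEGF receptor gene Kdr (1.19) rose and Myl7 fell (−1.07) among 18, against 3 up and 1 down with p adjusted over the list alone. Its median was −0.23 and its mean 0.02, and camera pointed downwards (adjusted p = 0.956). Among 13 neural ectoderm genes the Notch ligand gene Dll1 rose (2.68) and Nefl fell (−1.07), against 1 up and 2 down with p adjusted over the list alone (median 0.02, camera adjusted p = 0.818). Among 19 trophectoderm genes Krt7 (1.63) and Fgfr2 (1.02) rose and Tead4 (−1.29) and Elf5 (−1.63) fell, against 7 up and 3 down with p adjusted over the list alone (median 0.15, camera adjusted p = 0.0950). The trophectoderm median was 0.58 without control 1, where camera passed (adjusted p = 0.0438), and −0.06 without control 2 (0.460), and camera passed over bright probes too (0.0434). Elf5 was well above background on 1 of the 2 knock-down arrays and turned to 0.12 under normexp, where Sox7 had a change of −0.21, Cubn one of 0.53 and Fgfr2 one of 0.64, all without a call. Those of Wnt3 (1.32), Kdr (0.75) and Krt7 (0.99) were smaller there and passed. Within slide 1 the calls of Sox7, Wnt3, Dll1 and Krt7 held, and those of Cubn (adjusted p = 0.132), Lama1 (0.434), Kdr (0.171), Myl7 (0.310), Nefl (0.384), Fgfr2 (0.441), Elf5 (0.384) and Tead4 (0.172) ended. Except for Elf5 they ended without knock-down 1 too (0.0652 to 0.311), and that of Elf5 without control 1 (0.0754), without control 2 (0.119) and with quantile normalization (0.0788). With the mean over its probes that of Fgfr2 ended (0.0511). None of 10 fibroblast markers passed, adjusted over the list alone included, and Acta2 (−0.10) and Fn1 (−0.015) each had every other probe the opposite way. Their median was 0.08 and their mean −0.02 (camera Up, adjusted p = 0.873).

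Among cell cycle genes, the CDK inhibitor and senescence list passed, where 3 of 12 members rose and 4 did with p adjusted over the list alone (median 0.21, camera adjusted p = 0.0124, and adjusted p = 0.820 with an estimated correlation). Its median was 0.37 without control 1 and 0.10 without control 2, and camera passed in both (highest adjusted p = 0.0438). Cdkn2b, which encodes the CDK4 inhibitor p15, rose 5.93-fold and the retinoblastoma gene Rb1 4.34-fold. None of 39 DNA replication and G1/S genes passed, adjusted over the list alone included, with 33 lower, a median of −0.18 and a camera adjusted p of 0.0512. That list passed in 8 of 17 alternatives, without control 2 (median −0.28, adjusted p = 0.0101) and under normexp (0.00159) among them, and its highest adjusted p was 0.259. Ccne1 had a change of −0.29 and Mcm6 one of −0.24. None of 39 mitosis genes passed, adjusted over the list alone included, with Cdc20 at 0.17, Birc5 at −0.10 and a median of −0.12 (camera adjusted p = 0.378, and 0.0322 under normexp). None of 26 apoptosis regulators passed, adjusted over the list alone included, with Cycs at −0.15, Mcl1 at −0.18 and a median of −0.11 (camera adjusted p = 0.743).

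In metabolism and signalling, Vegfa and the phosphofructokinase gene Pfkp (−1.33) fell among 29 glycolysis and hypoxia genes, and 4 did with p adjusted over the list alone (median −0.21, camera adjusted p = 0.0850). That list passed in 6 of 17 alternatives, namely under normexp (adjusted p = 3.53e-04), over bright probes (0.0446), with trend and with trend and robust (0.0371 each), without control 2 (median −0.37, adjusted p = 0.00667) and unfiltered with trend (0.00692). Its median was −0.04 without control 1 (adjusted p = 0.762). None of 44 oxidative phosphorylation genes passed, adjusted over the list alone included (Cox6a1 0.21, Atp5b 0.07, median −0.13, camera adjusted p = 0.285), and the list passed without control 2 (−0.26, adjusted p = 0.00667) and under normexp (0.010) and had a median of 0.001 without control 1. None of 20 sterol synthesis genes passed, adjusted over the list alone included (Fdps −0.05, median −0.26, camera adjusted p = 0.118), and the list passed without control 2 (−0.40, adjusted p = 0.0363) and under normexp (0.0386) and had a median of −0.13 without control 1. None of 15 LIF and STAT3 target genes passed, adjusted over the list alone included (Socs3 0.01, Sgk1 −0.39, median −0.35, camera adjusted p = 0.175). The LIF and STAT3 median was −0.06 without control 1 (adjusted p = 0.573) and −0.36 without control 2, where camera passed (0.0227), as it did under normexp (0.0443). In the MYC family Mxd4, an antagonist of MYC, rose (1.32) and Myc fell 1.98-fold (log2 −0.98 ± 0.23, adjusted p = 0.0299), against 2 up and 1 down of 17 with p adjusted over the list alone. The list's median was −0.14 and its mean −0.06 (camera adjusted p = 0.80). The other probes of Myc gave −1.01 and −0.74, and within slide 1 the calls of Myc (adjusted p = 0.604), Mxd4 (0.130) and Pfkp (0.150) ended. Without knock-down 1 those of Myc (0.269) and Mxd4 (0.0635) ended, and with the mean over its probes that of Pfkp (0.0512).

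**Figure D3:**
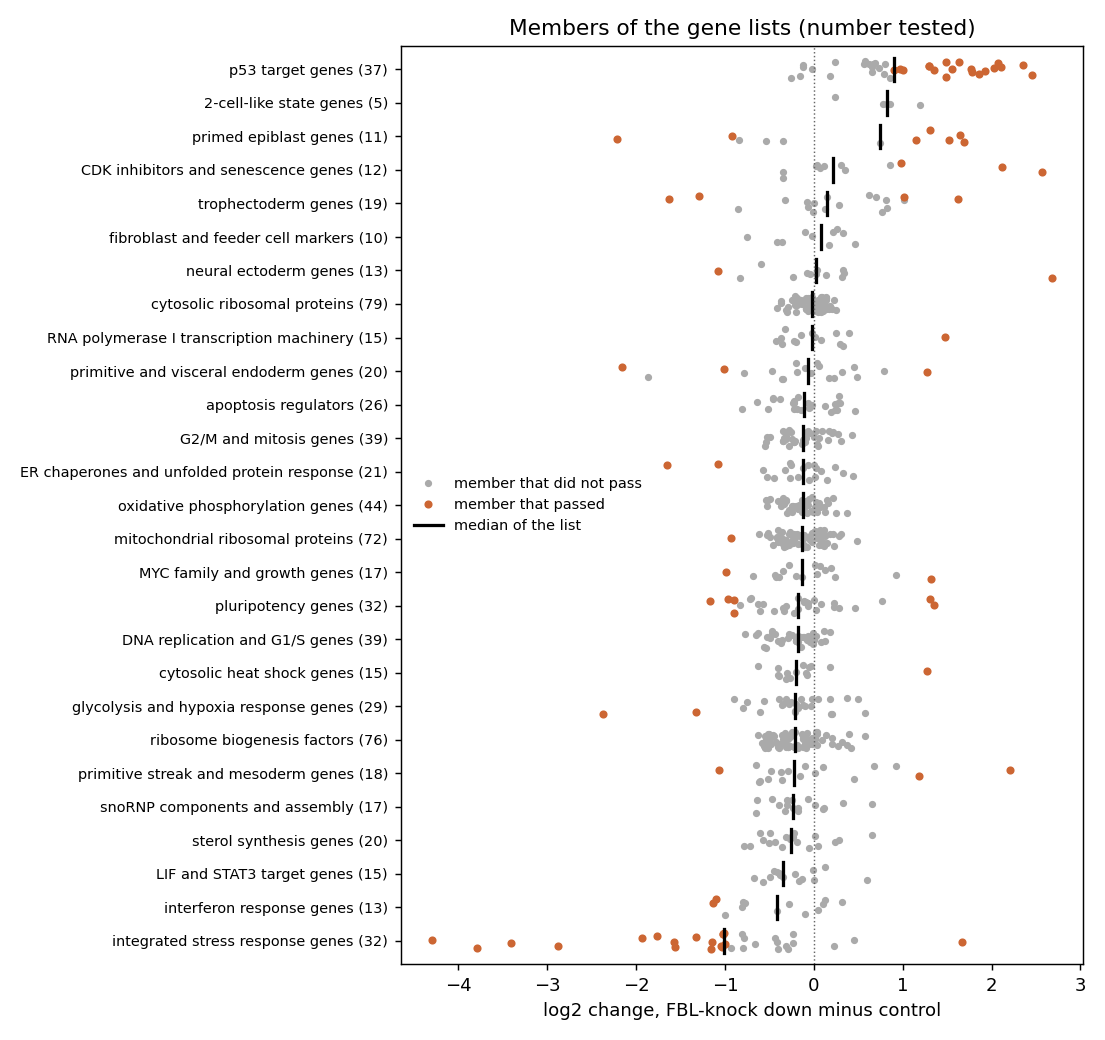
Log2 change, knock-down minus control, of each tested member of the 27 tested gene lists, ordered by list median; each point is 1 gene, coloured where it passed the adjusted threshold over all genes, and each bar is the list's median. The medians run from −1.01 for the integrated stress response genes to 0.90 for the p53 target genes.

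Of the 27 lists, 5 passed camera with the preset correlation and 0 with an estimated one, and 16 passed under normexp. The smallest adjusted p of camera with an estimated correlation was 0.484. Its 2 residual degrees of freedom raise p even where the estimated correlation is below 0. For the 2-cell-like list, with −0.063, the unadjusted camera p went from 4.07e-04 to 0.069. A loss there therefore does not tell whether correlated members explain a shift. Against random lists matched on level, the medians of the p53, primed epiblast, 2-cell-like and CDK inhibitor lists lay at percentiles 100, 99.99, 99.6 and 98.0. Those of the stress response, ribosome biogenesis, LIF and STAT3, interferon, sterol synthesis and glycolysis lists lay at 0, 0.03, 0.50, 0.52, 1.45 and 2.14. Those of the other 17 lists lay between 4.16 and 95.9. The random lists were matched on level and not on correlation. A difference between arrays that correlated members share can therefore also give an extreme percentile. Tc was present in both controls and absent from both knock-down samples, so its own effect and that of the knock-down cannot be told apart.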

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

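All alternatives were planned except the unfiltered fit with trend, which was chosen after the data were seen. The 17 settings are not 17 separate checks, because the slide as a block and the fit without knock-down 2 are the same fit. Median scaling, and nearly all entries of the authors' value table, differ from the main values by a constant per array. Fbl stayed lower in all 17 settings, from −2.67 to −2.16, and passed in 16, the exception being the fit with no filter (−2.42, adjusted p = 0.108). The p53 list (median 0.83 to 1.05, adjusted p up to 2.60e-11), the stress response list (−1.16 to −0.76, up to 9.76e-07) and the CDK inhibitor list (up to 0.0438) passed in all 17 settings with the preset correlation, the 2-cell-like list in 14 of 16 and the interferon list in 7 of 17. With an estimated correlation 0 lists passed. Of the lists without a call, DNA replication and G1/S genes passed in 8 settings, ribosome biogenesis factors in 7 and glycolysis and hypoxia genes in 6. Mitochondrial ribosomal proteins, trophectoderm, oxidative phosphorylation, sterol synthesis and LIF and STAT3 target genes passed in 2 each, and cytosolic ribosomal proteins in 1 upwards and 1 downwards. Of 63 named called genes, 62 kept their direction in every alternative, Elf5 being the exception, and 900 of the 1061 values passed. A replicate left alone in its group was assumed to vary like the other group. Dim signal limits the folds given as bounds. The higher calls were 59.7% of all calls, and no scaling moved that share by more than 10 points. With a change of 1 on the log2 scale 16% of simulated genes were recovered. The data gave 1238 calls against 117 in the simulation, so that share need not hold for them. No change under 0.87 was called in the main fit, so smaller changes may have been missed.

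Counts of higher and lower genes were 1168 and 982 with trend and robust, 380 and 195 with the slide as a block, and 1280 and 1193 without filter but with trend; trend alone gave 811 lower genes. With no filter they were 0 and 0 (2967 genes at unadjusted p under 0.05 in limma) over 32940 genes, where the estimated prior carried 3.45 degrees of freedom against 7.89. Lists passing were 16 under normexp and 8 with trend and with trend and robust. Leaving out 1 array gave 380 to 2379 higher genes, 195 to 1801 lower genes and 4 to 12 lists. Under normexp 61 called genes changed sign, 11 of them well above background on all arrays against 909 of the 1238 calls, and 0 passed the other way. With the replicate block, 958 genes were higher and 788 lower and 4 lists passed; deviations of same-numbered samples correlated at 0.0029 across genes, so the numbers do not pair the samples. Except where stated, the cause was not tested.

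These values changed sign, and the cause was not tested. Quantile normalization gave −0.010 for cytosolic ribosomal proteins, 0.019 for Pou5f1, −0.014 for Rps18, −0.010 for Rpl7a, 0.033 for Fn1 and 0.013 for Fdps. The 75th percentile over probes well above background on all arrays gave 0.041 for Fn1 and 0.0014 for Fdps. Normexp background correction gave −0.18 for the RNA polymerase I transcription machinery, −0.047 for cytosolic ribosomal proteins, 0.0051 for primitive streak and mesoderm genes, 0.041 for fibroblast and feeder cell markers, −0.083 for Snhg3, 0.12 for Elf5 and −0.011 for Socs3; for the lists, the sign is that of the camera test. No filter gave 0.036 for primitive and visceral endoderm genes and −0.13 for primitive streak and mesoderm genes, and so did the unfiltered fit with trend for the latter. Probes well above background on all arrays gave −0.014 for cytosolic ribosomal proteins and −0.13 for primitive streak and mesoderm genes. The mean over probes gave −0.017, −0.20 and, for Fn1, 0.018. Trend, trend and robust, and the replicate block each gave −0.23 for primitive streak and mesoderm genes. The slide as a block gave −0.044 for cytosolic ribosomal proteins, −0.24 for primitive streak and mesoderm genes, −0.0039 for fibroblast and feeder cell markers, −0.0083 for Nhp2, −0.046 for Ppan, 0.021 for Fn1 and −0.032 for Atp5b.

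Leaving out each array in turn gave these ranges, and the cause was not tested: primitive streak and mesoderm genes −0.39 to 0.0068, oxidative phosphorylation genes −0.26 to 0.0014, cytosolic ribosomal proteins −0.20 to 0.21, fibroblast and feeder cell markers −0.12 to 0.28, Pou5f1 −0.34 to 0.21, Acta2 −0.39 to 0.20, Fn1 −0.11 to 0.078, Ccne1 −0.62 to 0.048, Birc5 −0.23 to 0.022, Fdps −0.29 to 0.18, Nhp2 −0.15 to 0.36, Npm1 −0.25 to 0.044, Ppan −0.25 to 0.31, Rps18 −0.16 to 0.31, Rpl7a −0.13 to 0.36, Snhg3 −0.070 to 0.095, Cdc20 −0.17 to 0.50, Cox6a1 −0.056 to 0.48, Atp5b −0.15 to 0.29 and Socs3 −0.25 to 0.27.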

Other observations

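The tests of explanations in this part, and the synthetase, Wnt and Notch gene sets, were chosen after the results were seen, while the fits that leave out an array, the scalings and camera with an estimated correlation were planned for the p53 and stress response lists; for the Wnt ligand genes a second form of test was added after the first had left the matter open. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge transfer RNAs for translation in the cytosol, 6 fell and 19 were lower. Nars fell by 1.57, Aars by 1.14, Yars by 1.13, Iars by 1.03, Gars by 1.02 and Sars by 0.998 on the log2 scale; Nars, Aars, Gars and Sars are also members of the stress response list. The median of the set was −0.73 (bootstrap interval −0.96 to −0.41, camera adjusted p = 1.61e-07, and adjusted p = 0.107 with an estimated correlation). Each bootstrap interval in this part is a 95% interval that resamples the members of a list or set. It holds no spread between samples and treats members as independent, so it may be too narrow where members are correlated. Of 16 synthetase genes for mitochondrial translation 0 passed in limma, and their median was −0.10 (−0.17 to 0.049, camera adjusted p = 0.958). Within slide 1, Nars was the only 1 of the 6 to pass, as it was without knock-down 1.

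Of 14 measured Wnt ligand genes 7 rose and 0 fell: Wnt3 (2.21), Wnt9a (1.32), Wnt6 (1.28) and Wnt10a (1.20), then Wnt8a, which was well above background on 1 of the 2 control arrays, and Wnt5a at least 4.53-fold and Wnt8b at least 2.09-fold from controls not well above background. Among 10 genes that respond to canonical Wnt signalling, Lef1 rose (1.15), while Axin2 (−0.73, adjusted p = 0.0973), Sp5 (−0.71, adjusted p = 0.143) and T (−0.51) did not pass, and the median was −0.18 (camera adjusted p = 0.983). The 4 measured Notch ligand genes all rose, namely Dll1 (2.68), Dll3 (1.83), Jag2 (1.13) and Jag1 (1.06). Of 4 Notch target genes Nrarp rose (1.03), and Hes1 (−0.68), Hes5 (−0.59) and Hey1 (−0.06) did not pass. Within slide 1, Wnt3, Wnt5a, Wnt8a, Wnt8b, Dll1 and Dll3 passed and the other rising genes of these sets did not, nor did they without knock-down 1. Under normexp Wnt8b (0.43) and Nrarp (0.68) did not pass, and Wnt8a (2.19), Wnt5a (0.83, below its bound of 2.18 on the log2 scale), Wnt3 (1.32), Wnt9a (0.74) and Lef1 (0.76) passed with smaller changes.

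The p53 targets rose together, which may reflect p53 activity after loss of FBL, a hypothesis that these samples do not test, since p53 was not changed apart from the knock-down. A single array does not account for it, since the highest adjusted p of the list with each array left out was 2.60e-11. The rise also stayed under scaling that depends on signal, which quantile normalization and normexp change. The list median minus the median of all genes, in which a constant shift of an array cancels, was measured under both. The lower of the 2 values was 0.82 (bootstrap interval over members 0.60 to 1.09). The absence of tetracycline itself cannot be told apart from the knock-down, because 0 samples separate them. All of these p-values use the preset correlation, and the call was lost with adjusted p = 0.484 with an estimated correlation.

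The stress response genes fell together, and 2 candidate explanations are the knock-down and the removal of Tc, since tetracyclines inhibit mitochondrial translation, which can raise ATF4 activity. The absence of tetracycline itself cannot be told apart from the knock-down, because 0 samples separate them. A single array does not account for the fall, with a highest adjusted p of 9.76e-07 with each array left out, against 0.820 with an estimated correlation and all arrays. Relief of a general unfolded protein response would lower the list of chaperones and unfolded protein response genes about as far, but its median was −0.12 (−0.27 to 0.016) against an interval of −1.10 to −0.66 for the stress response list. In that list Herpud1 (−1.65) and Dnajc3 (−1.08) fell, and it passed downwards under normexp (median −0.17, adjusted p = 0.0210), so relief in part stays open.

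The Wnt ligand genes had a median of 1.02 (0.95 with Wnt5a and Wnt8b at their bounds) and were the only 1 of 152 gene families formed by symbol to pass camera (adjusted p = 1.22e-05, and adjusted p = 0.997 with an estimated correlation), and they differed by −0.69 between control 2 and control 1. Low values on control 2 alone could contribute: against control 1 only, the median was 0.71, with a bootstrap interval that includes 0 (−0.19 to 1.88). Probes near background could too, since the 11 members well above background on all arrays had a median of 0.65 (−0.18 to 1.28). Normexp lowered the median of all 14 to 0.46, with 13 of them higher. Its offset shrinks the change of any dim gene, so that drop does not decide whether background contributes. After both had come out open, camera with the preset correlation was also run without control 2 (adjusted p = 7.13e-04) and over genes well above background on all arrays (adjusted p = 1.96e-04); as this second form was picked with the first in view, both explanations are left open. Induction by p53 stays open as well, because 0 samples change p53 apart from the knock-down.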
